A study of Mus musculus with 24 samples.

How the data were processed

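Per the labels and the processing notes of the submitters, cortical neural progenitor cells were isolated from C57BL/6 embryos at embryonic day 12 and expanded with B27 and basic fibroblast growth factor. At passage 3 they were placed in differentiation medium with either enantiomer of JQ1. Total RNA was treated with DNase, selected for poly(A) and primed with random hexamers, and 50-base single-end reads were sequenced on an Illumina HiSeq. The reads were checked with FastQC and aligned with TopHat2 to the mouse genome build mm9; their versions were not given in the sources used here. The deposited values are FPKM per gene symbol, as the authors processed them. The program that computed the FPKM, the annotation, and any scaling between libraries were not given in the sources used here. Genes are named by the symbols of the files, which give no other identifier and no positions.

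Each of the 24 files held 26694 genes in the same order. 58 entries of 29 repeated symbols were left out, which left 26636 genes. Read counts were not used here, so no test on counts was run. Values were analysed as log2(FPKM + 1), which understates the fold change of genes with low values. Genes with at least 1 FPKM in at least 3 libraries were tested, 13801 in all, 174 of them genes of short RNAs.

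The main test was limma 3.58.1 in R 4.3.3, with 1 mean for each of the 8 groups, 16 residual degrees of freedom, and empirical Bayes moderation with a trend on the mean and robust settings. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. 13 comparisons were made: (+) against (−)-JQ1 at each dose and time, the difference of this effect between doses at each time and between times at each dose, 0.5 against 0.2 µM within each enantiomer at each time, and 24 against 12 h within (−)-JQ1 over both doses. The spread is therefore shared by all 24 libraries. The numbers 1 to 3 in the titles were not taken to pair samples across groups, which was decided before fits with and without pairing were compared.

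25 gene lists were written from general knowledge: proneural and neurogenic factors, neuronal cytoskeleton and synapse, interneuron and ganglionic eminence, astrocyte, oligodendrocyte lineage, neural stem and radial glia, Notch pathway, gliogenic JAK-STAT and BMP signalling, S phase and DNA replication, G2 and mitosis, G1 cyclins and CDK inhibitors, Myc family and targets, BET proteins and P-TEFb, histone genes, immediate early genes, p53 targets and apoptosis, integrated and unfolded protein stress, cholesterol synthesis and uptake, extracellular matrix and adhesion, interferon response, microglia, endothelium, pericyte and fibroblast, erythroid, and ependyma and choroid plexus. For each list, the members called over all genes were counted, and again with p adjusted over the list alone. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data, which allows for members that vary together. The rotation test fry was an alternative.

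The comparisons, gene lists, test, threshold and rule for naming genes were chosen before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall in each of the 4 main comparisons, among called genes that changed the same way in all 3 same-numbered pairs. It also named 4 and 4 in each other comparison, 3 members of each called list, and 21 genes fixed in advance. Its minimum of 50 counts could not be used, and a mean of at least 5 FPKM with short RNAs left out took its place after the unit was known. Results for some of the genes the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

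Relative depth was read from the steps between low FPKM values. In 1823 of 2312 genes above 0 in 5 to 16 libraries, every value was within 1% of a whole multiple of a common step after a factor per library. GC content and transcript length from the reference were known for 13046 of the genes tested (94.5%). The GC alternative removed a smooth curve with a span of 0.3 from each library and covers those genes. The curve includes each library's overall level, so this step also recentres the libraries. Counts that moved with it cannot be assigned to GC content alone. The median-of-ratios alternative divided each library by its median ratio to the geometric mean over libraries.

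As a self-test, normal values were simulated from each gene's mean and residual spread in these libraries, and known changes were added. Of the 13801 genes in it, 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. The shares recovered concern those genes and were not shown for genes with low values. In the comparison of the enantiomers at 0.5 µM and 24 h, 49.3%, 94.0% and 100% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, with 15 unchanged genes called. For the difference of the effect between doses at 24 h the shares were 31.3%, 73.1% and 98.5%, with 10 unchanged genes called. In the self-test a gene had the same spread in every library, and genes were drawn independently. It therefore carried neither the GC trends nor the unequal spread of the real libraries. Its unchanged genes called may therefore understate false calls. Wrong groupings of the real libraries called up to 2328 genes for the enantiomers at 0.2 µM and 24 h. For the doses of (−)-JQ1 at 24 h they called up to 1839.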

Results

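Neural progenitor cells are dividing cells of the embryonic cortex that can form neurons, astrocytes and oligodendrocytes. Here such cells from C57BL/6 mice, expanded with basic fibroblast growth factor and used at passage 3, were placed in differentiation medium with (+)-JQ1 or (−)-JQ1. (+)-JQ1 is a small molecule that occupies the acetyl-lysine pocket of the BET bromodomain proteins, readers of acetylated histones that recruit the elongation factor P-TEFb. (−)-JQ1 is its mirror image and served as the inactive control compound. Each enantiomer was given at 0.2 or 0.5 µM for 12 or 24 h, which gives 8 groups of 3 libraries from independent preparations, 24 libraries in all. The title of the series concerns how blocking BET bromodomains affects the formation of neurons and of glia. The values were FPKM, which do not carry the number of reads, so the absolute depth of the libraries is unknown. The steps between low values put the relative depth of the libraries between 0.939 and 1.05, a ratio of 1.12 between the largest and the smallest. FPKM summed to 432235 to 871177 per library (median 472543), and 16987 to 18243 genes per library had a value above 0. The highest sums came from the first (−) library and the second (+) library at 0.2 µM and 24 h. In them the microRNA gene Mir5105 took 42.7% and 46.9% of the sum, against at most 6.69% in the other 22 libraries. Genes above 0 numbered 17498 ± 84.8 in (+) and 18147 ± 58.2 in (−)-JQ1 at 12 h, and 17236 ± 169 and 17915 ± 210 at 24 h (SD, n = 6 each).

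The first comparison, (+) against (−)-JQ1 at 0.2 µM and 12 h, asks what blocking BET bromodomains does to these cells early and at the lower dose. Hexim1, whose product holds P-TEFb inactive and whose RNA is a usual readout of BET inhibition, was at 54.2 ± 4.90 FPKM in (+) and 18.2 ± 1.21 in (−)-JQ1 (SD, n = 3 each), a log2 fold change of 1.52 ± 0.09 (SE, adjusted p = 5.04e-11). Myc, a growth regulator whose transcription depends on BET proteins in many cells, fell from 31.3 ± 5.59 to 13.8 ± 3.04 FPKM (log2 -1.13 ± 0.14, adjusted p = 2.46e-06). Gpr17, a receptor of immature oligodendrocytes, fell from 370 ± 25.9 to 36.2 ± 13.4 FPKM (log2 -3.37 ± 0.21), and Enpp6, a phosphodiesterase of newly forming oligodendrocytes, changed by log2 -2.70 ± 0.13. The histone genes Hist1h4k (log2 2.95 ± 0.36) and Hist2h2bb (log2 2.87 ± 0.31) were among those that rose most. S100a16, which codes for a calcium-binding protein, fell by 3.72 ± 0.32 and the axon guidance receptor gene Plxnb3 by 3.42 ± 0.20 on the log2 scale. With limma, 3846 of 13801 genes passed an adjusted p of 0.05, 1136 higher and 2710 lower. At least 2-fold apart were 99 and 529 of them. The split moved to 1735 higher and 2311 lower when libraries were scaled by the median of ratios, to 2047 and 2266 with each library's trend on GC content removed, and to 1773 and 3594 with library weights.

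At 0.5 µM and 12 h, Hexim1 stood at 69.0 ± 3.34 against 18 ± 1.57 FPKM (SD, n = 3 each; log2 1.88 ± 0.09, SE, adjusted p = 1.02e-12), and Myc at 9.88 ± 1.99 against 29.9 ± 3.03 (log2 -1.52 ± 0.14). Gpr17 was at 4.13 ± 1.30 FPKM in (+) and 362 ± 24.5 in (−)-JQ1 (log2 -6.17 ± 0.21, adjusted p = 1.17e-14). Enpp6 was at 0.317 ± 0.112 against 17.6 ± 1.34 FPKM (log2 -3.82 ± 0.13), and the glial extracellular matrix gene Tnr changed by log2 -3.98 ± 0.21. Hist2h2bb rose by log2 3.42 ± 0.31, and Txnip, which codes for an inhibitor of thioredoxin and of glucose uptake, by 2.52 ± 0.15. In this comparison 5281 genes passed, 1682 higher and 3599 lower, with 201 and 892 of them at least 2-fold apart. The split was 2581 and 3048 after median-of-ratios scaling, 2876 and 2926 with the GC trend removed, and 2578 and 4677 with library weights.

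At 0.2 µM and 24 h, Jag1, which codes for a Notch ligand, joined the genes with the largest rise, with 14.4 ± 2.09 FPKM in (+) and 1.83 ± 0.325 in (−)-JQ1 (SD, n = 3 each; log2 2.44 ± 0.13, SE, adjusted p = 1.42e-11). Hexim1 (log2 1.30 ± 0.09) and Hist2h2bb (log2 3.63 ± 0.31) were higher, and Myc (log2 -1.41 ± 0.14) and Gpr17 (log2 -2.73 ± 0.21) lower. Cd82, which codes for a tetraspanin of the cell membrane, fell by 3.64 ± 0.14, the uncharacterised gene 3110035E14Rik by 4.24 ± 0.15, and Enpp6 by 3.4 ± 0.13 on the log2 scale. With limma 4529 genes passed, 1523 higher and 3006 lower, with 103 and 703 of them at least 2-fold apart. The split was 2407 and 2498 after median-of-ratios scaling and 2779 and 2568 with the GC trend removed. Both libraries with high Mir5105 belong to these groups: without them 1743 genes were higher and 2698 lower. A fit to the 6 libraries of this comparison alone called 2056 genes, 426 higher and 1630 lower.

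At 0.5 µM and 24 h, Enpp6 was nearly lost in (+)-JQ1, at 0.211 ± 0.0921 FPKM against 47.4 ± 8.41 in (−)-JQ1 (SD, n = 3 each; log2 -5.31 ± 0.13, SE, adjusted p = 6.06e-17). Gpr17 (log2 -5.38 ± 0.21) and 3110035E14Rik (log2 -5.50 ± 0.15) had similar log2 changes. Scrg1, a gene of glial cells, was lower by less (log2 -4.48 ± 0.19). Jag1 rose by log2 2.99 ± 0.13, Hist1h4k by 3.47 ± 0.36 and Hexim1 by 1.67 ± 0.09, and Myc fell by 2.14 ± 0.14. Here 5273 genes passed, 1893 higher and 3380 lower, with 170 and 1042 of them at least 2-fold apart. The split was 2601 and 3014 after median-of-ratios scaling and 2942 and 2992 with the GC trend removed. In these 4 comparisons median-of-ratios scaling moved the median of all genes by at most 0.0962 on the log2 scale. The fold changes correlated weakly with GC content across genes (Spearman rho -0.0515 to -0.101; genes are not independent replicates).

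**Figure D1:**
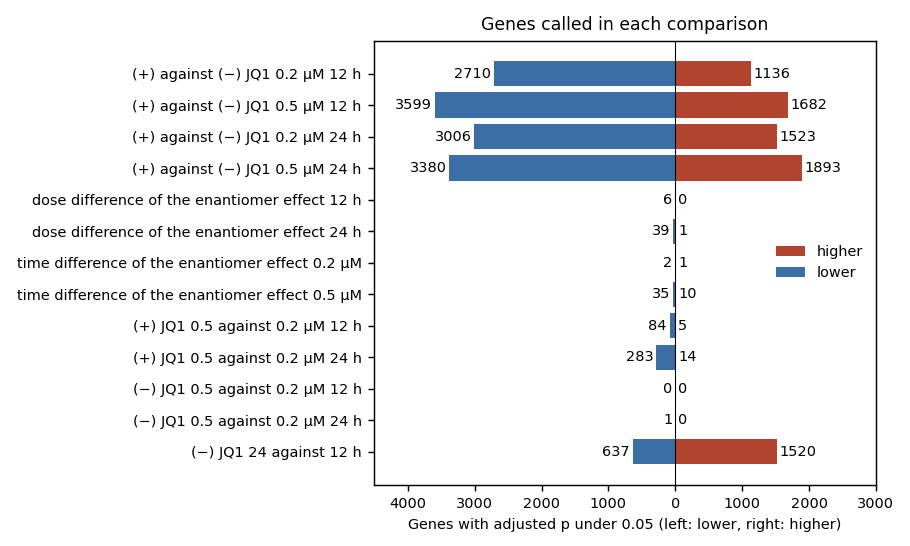
Number of genes with an adjusted p under 0.05 (limma, 13801 genes tested) in each of the 13 comparisons, lower genes to the left and higher genes to the right of 0. The 4 comparisons of the enantiomers call 3846 to 5281 genes, and the differences of these effects between doses or times at most 45.

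**Figure D2:**
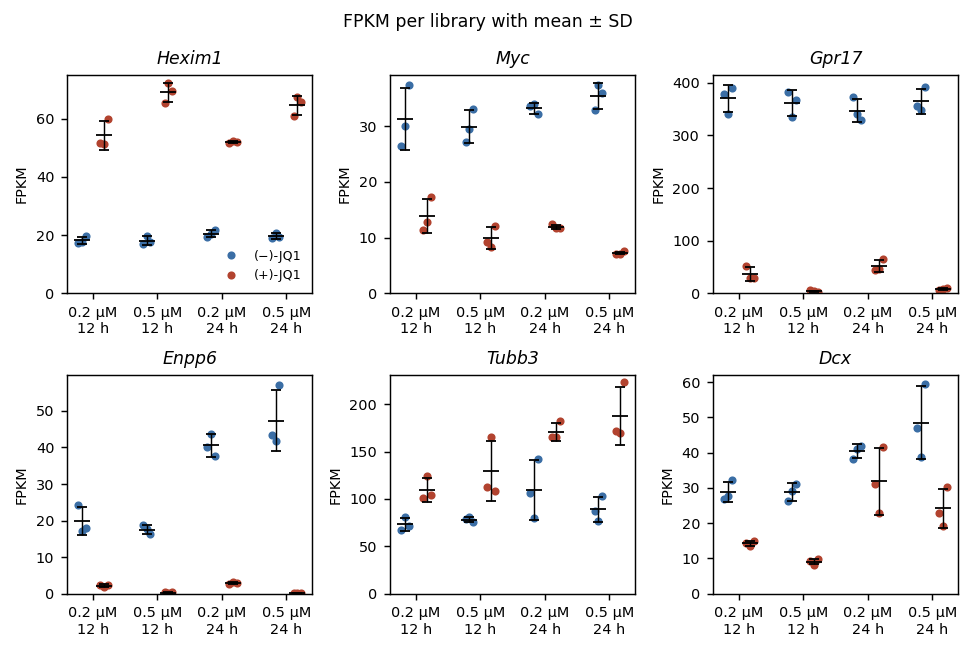
FPKM of 6 genes in each library of (−)-JQ1 (blue) and (+)-JQ1 (red) by dose and time; points are libraries, and black bars the mean ± SD of 3. Hexim1 and Tubb3 have higher means and Myc, Gpr17, Enpp6 and Dcx lower means in (+)-JQ1 at each dose and time; for Dcx at 0.2 µM and 24 h the difference did not pass the test.

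The genes of the oligodendrocyte lineage, which mark its precursors and its myelin-forming cells, were lower in all 4 comparisons. Of 21 measured members, 17, 18, 17 and 19 were lower in the order 0.2 µM 12 h, 0.5 µM 12 h, 0.2 µM 24 h and 0.5 µM 24 h, and 0 were higher. The counts were the same when adjusted over the list alone. Pdgfra, the growth factor receptor of oligodendrocyte precursors, changed by log2 -0.74 ± 0.10, -1.42 ± 0.10, -0.57 ± 0.10 and -1.29 ± 0.10 (SE). Olig2, a transcription factor of the lineage and of its progenitors, passed at 0.5 µM only, with log2 -0.66 ± 0.11 at 12 h and -0.82 ± 0.11 at 24 h, against -0.09 ± 0.11 and -0.22 ± 0.11 at 0.2 µM. The difference between the doses did not pass for Olig2 (log2 -0.57 ± 0.16, adjusted p = 0.518, and -0.60 ± 0.16, adjusted p = 0.176). Its relative Olig1 passed in none of the 4, with values from log2 -0.05 ± 0.29 to -0.48 ± 0.29. The median of the list was -1.25, -1.62, -1.04 and -1.89. Camera gave adjusted p = 7.06e-11, 5.15e-14, 3.6e-08 and 1.37e-15, with adjusted p = 0.0132, 0.00829, 0.0422 and 0.00445 with an estimated correlation.

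Astrocyte genes split. Of 21 measured, 9, 11, 9 and 12 were lower and 1, 1, 1 and 2 higher in the same order. Adjusted over the list alone, 10, 12, 9 and 12 were lower and 1, 1, 1 and 2 higher. At 0.2 µM and 24 h, 2 were higher after median-of-ratios scaling or with the GC trend removed and 3 without the 2 libraries with high Mir5105. Gfap, the intermediate filament of astrocytes, fell by log2 0.65 ± 0.13, 1.07 ± 0.13, 0.97 ± 0.13 and 0.99 ± 0.13, at 24 h and 0.5 µM from 440 ± 48.8 to 220 ± 20.3 FPKM (SD, n = 3 each). The water channel gene Aqp4 fell by 1.97 ± 0.19, 2.93 ± 0.19, 1.85 ± 0.19 and 3.39 ± 0.19, and S100b, which codes for a calcium-binding protein of astrocytes and oligodendrocytes, by 2.42 ± 0.21, 2.79 ± 0.21, 2.85 ± 0.21 and 4.01 ± 0.21. Slc1a3, a glutamate transporter of radial glia and astrocytes, did not pass, with log2 0.06 ± 0.19, 0.05 ± 0.19, 0.40 ± 0.19 and 0.25 ± 0.19. Its 95% interval at 0.5 µM and 24 h was -0.15 to 0.65. Camera called the list lower at 12 h (adjusted p = 0.0273 and 0.0187) and at 0.5 µM and 24 h (0.0317), not at 0.2 µM and 24 h (0.122). The adjusted p = 0.585, 0.562, 0.427 and 0.565 with an estimated correlation for the same comparisons. Without the 2 libraries with high Mir5105, the call at 0.5 µM and 24 h ended (adjusted p = 0.0763). Among 20 genes of gliogenic JAK-STAT and BMP signalling, 6, 8, 10 and 9 were lower and 3, 4, 3 and 3 higher (7, 8, 10 and 9 lower and 3, 4, 3 and 3 higher when adjusted over the list alone). With the GC trend removed, 5 were lower at 0.5 µM and 12 h and 5 higher at each dose at 24 h. Camera did not call the list (adjusted p 0.14 to 0.655). 3 of its members were chosen after their values were seen. Id3, a BMP target that inhibits proneural factors, changed by log2 -1.46 ± 0.35, -2.11 ± 0.35, -2.09 ± 0.35 and -2.80 ± 0.35. The BMP ligand gene Bmp4 changed by -1.87 ± 0.21, -2.46 ± 0.21, -1.90 ± 0.21 and -2.66 ± 0.21, and the cytokine receptor gene Il6st by 0.71 ± 0.09, 0.86 ± 0.09, 0.64 ± 0.09 and 0.58 ± 0.09.

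Genes of the neuronal cytoskeleton and the synapse went both ways. Of 23 measured, 3, 5, 4 and 3 were higher and 10, 13, 7 and 9 lower (4, 6, 5 and 3 higher and 11, 13, 7 and 9 lower when adjusted over the list alone). Removing the GC trend gave 5 higher at 0.2 µM and 12 h. Tubb3, the neuronal beta-tubulin, rose by log2 0.57 ± 0.18, 0.69 ± 0.18, 0.68 ± 0.18 and 1.07 ± 0.18, at 0.5 µM and 24 h from 88.9 ± 13.2 to 188 ± 30.5 FPKM (SD, n = 3 each). At 0.2 µM and 12 h its call ended without (−) replicate 1 (log2 0.51, adjusted p = 0.0785), (+) replicate 2 (0.48, 0.0966) or (−) replicate 3 (0.56, 0.057), and at 0.2 µM and 24 h in the fit to the 6 libraries alone (adjusted p = 0.0863). Dcx, a microtubule protein of migrating young neurons, fell by 0.97 ± 0.18, 1.57 ± 0.18 and 0.98 ± 0.18 except at 0.2 µM and 24 h, where it changed by -0.37 ± 0.18 (adjusted p = 0.107). The effect on Dcx at 0.2 µM was not shown to differ between the times (0.59 ± 0.25, adjusted p = 0.999). Of members chosen after their values were seen, the growth cone gene Gap43 changed by log2 -2.04 ± 0.21, -2.36 ± 0.21, -2.12 ± 0.21 and -2.09 ± 0.21 and Syt1, the calcium sensor of synaptic vesicles, by 0.60 ± 0.12, 0.80 ± 0.12, 0.69 ± 0.12 and 0.97 ± 0.12. Camera did not call the list (adjusted p = 0.167, 0.131, 0.48 and 0.284).

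Among 15 proneural and neurogenic factors, 3, 5, 5 and 7 were higher and 2, 6, 2 and 3 lower (5, 5, 5 and 7 higher and 3, 6, 2 and 3 lower when adjusted over the list alone). At 0.2 µM and 12 h, 5 were higher and 1 lower after median-of-ratios scaling or with the GC trend removed. Limma called 0 of them lower at 0.2 µM and 24 h after median-of-ratios scaling, with the GC trend removed or without the 2 libraries with high Mir5105. Chosen after its values were seen, Insm1, a zinc finger factor of new neurons and basal progenitors, rose by log2 1.27 ± 0.20, 1.48 ± 0.20, 1.85 ± 0.20 and 2.06 ± 0.20 (SE). Neurod1, a differentiation factor of neurons, passed only at 0.5 µM and 12 h (log2 -0.51 ± 0.18, adjusted p = 0.0275), a call that ended without (+) replicate 1 (-0.47, 0.0848), (−) replicate 2 (-0.37, 0.145) or (+) replicate 3 (-0.52, 0.0576). Its effect was not shown to differ between doses or times (adjusted p at least 0.999). The list was not called (adjusted p = 0.167, 0.316, 0.0583 and 0.11). Of 14 interneuron and ganglionic eminence genes, 0, 2, 2 and 3 were higher and 2, 2, 4 and 4 lower (0, 1, 2 and 3 higher and 2, 1, 4 and 4 lower when adjusted over the list alone). Scaling by the median of ratios or removing the GC trend gave 2 higher at 0.2 µM and 12 h and 1 lower at 0.5 µM and 12 h. With the GC trend removed, 4 were higher at 0.5 µM and 12 h and at 0.2 µM and 24 h, where limma called 0 higher without the 2 libraries with high Mir5105. That list was not called either (adjusted p = 0.839, 0.718, 0.837 and 0.79). Its median, mean and test differed in sign in the first 3 comparisons (at 0.2 µM and 24 h a median of 0.06 and a mean of -0.20, with the test pointing up).

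Of 20 neural stem and radial glia genes, 6, 7, 6 and 13 were higher and 1, 2, 1 and 2 lower (7, 8, 10 and 13 higher and 1, 2, 1 and 2 lower when adjusted over the list alone). Nes, an intermediate filament of neural stem cells, rose by log2 0.79 ± 0.17 and 0.81 ± 0.17 at 12 h and by 0.61 ± 0.17 at 0.5 µM and 24 h, and did not pass at 0.2 µM and 24 h (0.44 ± 0.17, adjusted p = 0.0521). Sox2, a transcription factor of neural stem cells, did not pass, with log2 0.23, 0.17, 0.11 and 0.22 and 95% intervals that reached from -0.17 to 0.52 over the 4 comparisons. The list was called higher (adjusted p = 0.00512, 0.00641, 0.00133 and 0.000372), with adjusted p = 0.357, 0.33, 0.394 and 0.236 with an estimated correlation. With the GC trend removed, 14 members were higher at 0.5 µM and 12 h and 12 at 0.2 µM and 24 h (13 and 11 after median-of-ratios scaling). Of 16 Notch pathway genes, 7, 7, 9 and 10 were higher and 1, 3, 1 and 3 lower (8, 8, 9 and 10 higher and 1, 3, 1 and 3 lower when adjusted over the list alone). At 0.5 µM and 12 h, 11 were higher after median-of-ratios scaling or with the GC trend removed, and at 0.2 µM and 24 h, 2 were lower without the 2 libraries with high Mir5105. Jag1 led the rise. Hes5, a Notch target that holds progenitors undifferentiated, rose by log2 0.89 ± 0.27, 1.08 ± 0.27, 1.06 ± 0.27 and 1.27 ± 0.27, and Mfng, a glycosyltransferase that modifies Notch receptors, fell by 2.55 ± 0.19, 3.07 ± 0.19, 2.62 ± 0.19 and 2.43 ± 0.19. At 0.2 µM, the call of Hes5 at 12 h ended without (+) replicate 2 (adjusted p = 0.0595) or (−) replicate 3 (0.0752), and at 24 h in the fit to the 6 libraries alone (0.105). Hes1 passed only at 0.5 µM and 24 h (log2 0.62 ± 0.15, adjusted p = 0.00238), and its effect was not shown to differ between doses or times (adjusted p at least 0.97). The Notch list was called higher (adjusted p = 0.00512, 0.00907, 0.000965 and 0.00553), with adjusted p = 0.527, 0.562, 0.394 and 0.427 with an estimated correlation.

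Histone genes rose together. Of 20 measured, 17, 19, 17 and 19 were higher and 0 lower (18, 19, 18 and 19 higher when adjusted over the list alone), with medians of log2 1.5, 1.89, 1.36 and 1.56. H2afx, the variant histone of the DNA damage response, rose by 1.45 ± 0.12, 1.82 ± 0.12, 1.13 ± 0.12 and 1.56 ± 0.12, and Hist2h2aa1 by 1.69 ± 0.12, 2.38 ± 0.12, 1.52 ± 0.12 and 1.91 ± 0.12. The camera call (adjusted p = 2.14e-18, 1.4e-17, 6.08e-14 and 1.14e-14) held with an estimated correlation (adjusted p = 0.0132, 0.0125, 0.0422 and 0.0284). Many histone genes are near-identical copies, so the value of a single H4 gene is uncertain. The summed FPKM of 13 H4 genes was 168 ± 39.6 in (+) and 26.4 ± 14.3 in (−)-JQ1 at 0.2 µM and 12 h, 239 ± 34.5 and 38.8 ± 12.5 at 0.5 µM and 12 h, 221 ± 115 and 38.7 ± 5.49 at 0.2 µM and 24 h, and 223 ± 33.4 and 23.2 ± 7.04 at 0.5 µM and 24 h (SD, n = 3 each).

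Cell cycle genes were lower at 24 h. Of 21 genes of S phase and DNA replication, 14 were lower and 0 higher at 0.2 µM and 13 lower and 2 higher at 0.5 µM (15 and 1, and 14 and 2, when adjusted over the list alone). At 0.2 µM, 2 were higher after median-of-ratios scaling or with the GC trend removed. Cdc45, part of the replicative helicase, fell by log2 1.29 ± 0.15 and 1.52 ± 0.15, and Mcm3 by 1.59 ± 0.21 and 1.69 ± 0.21. Of 22 genes of G2 and mitosis, 14 were lower and 0 higher at each dose, also when adjusted over the list alone. At 0.2 µM, 6 were lower without the 2 libraries with high Mir5105. Mki67, the proliferation marker Ki-67, was at 2.26 ± 0.851 FPKM in (−) and 0.289 ± 0.172 in (+)-JQ1 at 0.2 µM (SD, n = 3 each; log2 -1.32 ± 0.30, SE, adjusted p = 0.00192) and changed by -1.59 ± 0.30 at 0.5 µM. Its effect differed between the times at 0.5 µM (log2 -2.01 ± 0.42, adjusted p = 0.0398) and was not shown to at 0.2 µM (-1.49 ± 0.42, adjusted p = 0.411). With library weights the call of Mki67 at 0.2 µM and 24 h ended (adjusted p = 0.05003). Camera called both lists lower at 24 h (S phase adjusted p = 0.000117 and 0.00566, mitosis 0.000965 and 0.00606), with adjusted p = 0.394, 0.427, 0.565 and 0.55 with an estimated correlation. At 12 h, 5 and 4 S phase genes were lower and 2 and 3 higher, the same counts when adjusted over the list alone, with adjusted p = 0.788 and 0.545. At 0.5 µM its median (-0.01) and mean (-0.05) lay below 0 and the test pointed up. At 12 h, 0 mitosis genes were called at 0.2 µM and 1 higher at 0.5 µM (0 and 0 when adjusted over the list alone), where 2 were higher after median-of-ratios scaling and 3 with the GC trend removed. Camera nevertheless called the list higher at 0.5 µM (median 0.34, adjusted p = 0.00999), with adjusted p = 0.668 with an estimated correlation. Among 15 G1 cyclins and CDK inhibitors, 2, 3, 2 and 2 were higher and 4, 5, 6 and 6 lower (2, 3, 2 and 2 higher and 5, 5, 7 and 7 lower when adjusted over the list alone). Removing the GC trend gave 4 higher at 0.2 µM and 12 h, 3 lower at 0.5 µM and 12 h and 5 higher at 0.5 µM and 24 h. The list was not called (adjusted p = 0.839, 0.936, 0.474 and 0.463). Ccnd1, which codes for the G1 cyclin D1, fell by log2 0.90 ± 0.21, 0.95 ± 0.21, 1.13 ± 0.21 and 1.12 ± 0.21. Cdkn1a, the CDK inhibitor p21, passed only at 0.2 µM and 24 h (log2 -0.98 ± 0.35, adjusted p = 0.0362), a call that ended when any 1 of the 6 libraries was left out (adjusted p 0.0646 to 0.0978). For Cdkn1a, too, the test did not show a difference between doses or times (adjusted p at least 0.999).

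**Figure D3:**
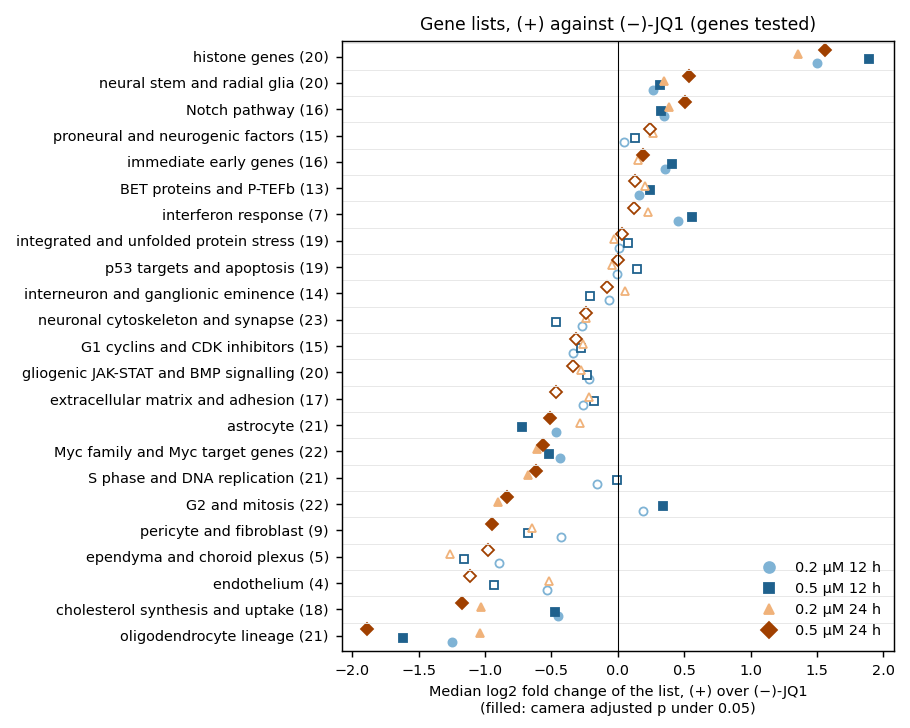
Median log2 fold change of (+) over (−)-JQ1 (horizontal axis) for each gene list with at least 2 genes tested (number in brackets), in the 4 comparisons; filled symbols mark a camera adjusted p under 0.05. Oligodendrocyte lineage genes have medians from -1.89 to -1.04 and histone genes from 1.36 to 1.89, and the mitosis list is above 0 at 12 h and below 0 at 24 h.

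The targets of Myc were mostly lower. Of 22 genes of the Myc family and its targets, 13, 14, 16 and 13 were lower and 1 higher in each comparison (13, 14, 18 and 14 lower and 1 higher when adjusted over the list alone). At 0.5 µM and 12 h, 2 were higher with the GC trend removed. Srm, a Myc target that codes for spermidine synthase, fell by log2 1.30 ± 0.16, 1.57 ± 0.16, 1.18 ± 0.16 and 1.27 ± 0.16. Odc1, which codes for the preceding enzyme of polyamine synthesis and is a Myc target too, was the member that rose, by 0.84 ± 0.12, 1.11 ± 0.12, 0.64 ± 0.12 and 0.98 ± 0.12. The list was called lower (adjusted p = 0.00512, 0.00854, 0.000226 and 0.00399), with adjusted p = 0.527, 0.562, 0.394 and 0.427 with an estimated correlation. Genes of cholesterol synthesis and uptake were lower as well, 8, 11, 15 and 17 of 18, with 0 higher (12, 12, 15 and 18 lower when adjusted over the list alone). Fdps, which codes for farnesyl diphosphate synthase, fell by log2 1.24 ± 0.20, 1.28 ± 0.20, 1.84 ± 0.20 and 1.99 ± 0.20, and Fdft1, which codes for squalene synthase, by 0.83 ± 0.17, 0.99 ± 0.17, 1.30 ± 0.17 and 1.72 ± 0.17. That list was called lower (adjusted p = 0.00512, 0.0163, 9.32e-07 and 1.32e-07), with adjusted p = 0.585, 0.629, 0.394 and 0.427 with an estimated correlation. At 0.5 µM and 12 h, 7 members were lower with the GC trend removed and 6 after median-of-ratios scaling, which gave 5 at 0.2 µM and 12 h.

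Of 13 genes of BET proteins and P-TEFb, 3, 4, 5 and 4 were higher and 1, 1, 2 and 2 lower (4, 4, 5 and 5 higher and 1, 1, 2 and 2 lower when adjusted over the list alone). Removing the GC trend gave 7 higher at 0.5 µM and 12 h. Scaling by the median of ratios gave 5 higher at 0.2 µM and 12 h and 1 lower at 0.2 µM and 24 h. Besides Hexim1, Brd2 rose by log2 0.59 ± 0.11, 0.77 ± 0.11, 0.55 ± 0.11 and 0.56 ± 0.11. Brd3 did not pass, with log2 -0.06, -0.17, -0.15 and -0.22 and a 95% interval of -0.28 to 0.17 at 0.2 µM and 12 h. The list was called higher at 12 h (adjusted p = 0.0169 and 0.0186) and not at 24 h (0.0716 and 0.0962), with adjusted p = 0.343, 0.33, 0.394 and 0.427 with an estimated correlation. Of 16 immediate early genes, which respond to stimuli without new protein synthesis, 7, 8, 5 and 6 were higher and 1, 2, 1 and 2 lower (7, 9, 5 and 6 higher and 1, 2, 2 and 2 lower when adjusted over the list alone). At 0.5 µM and 12 h, 1 was lower with the GC trend removed. Btg1, an antiproliferative factor, rose by 0.77 ± 0.10, 0.99 ± 0.10, 0.88 ± 0.10 and 1.24 ± 0.10. This list was called higher except at 0.2 µM and 24 h (adjusted p = 0.00107, 0.000693, 0.0716 and 0.0252), with adjusted p = 0.447, 0.412, 0.565 and 0.431 with an estimated correlation. Of 7 measured interferon response genes, 4, 4, 2 and 3 were higher and 1 lower in each, also when adjusted over the list alone. Those that rose included H2-K1 (1.23 ± 0.17 and 1.45 ± 0.17 at 12 h) and H2-D1, which code for antigen-presenting class I molecules. Ddx58, the viral RNA sensor of the list, fell by 0.74 ± 0.13 at 0.5 µM and 12 h. The list was called higher at 12 h (adjusted p = 0.0417 and 0.0187) and not at 24 h (0.292 and 0.172), with adjusted p = 0.343, 0.234, 0.525 and 0.427 with an estimated correlation. The call at 0.2 µM and 12 h ended after median-of-ratios scaling (0.089).

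The remaining lists were not called in most comparisons. Of 19 p53 targets and apoptosis genes, 4, 6, 4 and 4 were higher and 2, 2, 3 and 2 lower (5, 6, 4 and 4 higher and 2, 2, 3 and 2 lower when adjusted over the list alone; adjusted p 0.0968 to 0.48). Scaling by the median of ratios or removing the GC trend gave 1 lower at 0.2 µM and 12 h and 8 higher at 0.5 µM and 24 h. Median, mean and test differed in sign except at 0.5 µM and 12 h. Of 19 genes of integrated and unfolded protein stress, 5, 5, 3 and 4 were higher and 3 lower in each, also when adjusted over the list alone (adjusted p 0.213 to 0.758). At 0.5 µM, 8 were higher at 12 h after median-of-ratios scaling or with the GC trend removed, and 7 at 24 h with the GC trend removed. Without the 2 libraries with high Mir5105, 1 was higher at 0.2 µM and 24 h. At 0.2 µM and 24 h the median (-0.03) and mean (-0.05) were below 0 and the test pointed up. Of 17 extracellular matrix and adhesion genes, 0, 1, 1 and 0 were higher and 4, 5, 2 and 7 lower (0, 1, 1 and 0 higher and 4, 6, 2 and 8 lower when adjusted over the list alone; adjusted p 0.124 to 0.61). After median-of-ratios scaling or with the GC trend removed, 1, 2 and 2 were higher in the first 3 comparisons, and at 0.2 µM and 24 h, 1 was lower without the 2 libraries with high Mir5105. Markers of other cell types were few. Cd68 was the measured microglia gene of 14 and did not pass (log2 0.43, 0.23, 0.44 and 0.01), and 0 of 12 erythroid genes reached the level needed for testing. Of 4 endothelial genes, 1, 1, 1 and 0 were higher and 1, 2, 2 and 2 lower (1, 1, 1 and 0 higher and 1, 2, 2 and 3 lower when adjusted over the list alone; adjusted p 0.197 to 0.61). At 24 h, 1 was lower at 0.2 µM without the 2 libraries with high Mir5105 and 1 higher at 0.5 µM with the GC trend removed. Of 5 genes of ependyma and choroid plexus, 0, 1, 1 and 1 were higher and 4 lower in each (1 higher and 4 lower in each when adjusted over the list alone; adjusted p 0.0716 to 0.213). Foxj1, chosen after its values were seen, a factor of ciliated cells, fell by log2 1.24 ± 0.18, 1.59 ± 0.18, 1.57 ± 0.18 and 2.03 ± 0.18. Of 9 pericyte and fibroblast genes, 1, 1, 1 and 2 were higher and 4, 6, 6 and 6 lower (2, 1, 1 and 2 higher and 4, 6, 6 and 7 lower when adjusted over the list alone). After median-of-ratios scaling or with the GC trend removed, 2 were higher at 0.2 µM and 12 h. That list was called lower at 0.5 µM and 24 h (adjusted p = 0.0353; adjusted p = 0.427 with an estimated correlation) and not in the others (0.204, 0.171 and 0.0716). Acta2, the smooth muscle actin, fell there by log2 2.29 ± 0.15 and Pdgfrb, a pericyte receptor, by 1.73 ± 0.17.

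The 4 comparisons shared many of their genes. 806 genes were higher and 2019 lower in all 4, out of 2536 and 4498 called in any. The comparisons have no library in common, but their calls share 1 estimate of each gene's spread. Genes with a small spread are called more easily in each, which can raise the overlap above that of independent lists. Between the doses at 12 h, 1061 genes were higher in both, against 138 for independent lists of the same sizes, and 2569 lower in both, against 707. No gene was called in opposite directions between them. Across genes, which are not independent replicates, the fold changes of pairs of comparisons correlated with a Spearman rho of 0.793 to 0.907. Taking the 2569 genes lower at both doses at 12 h, the median change at 24 h was log2 -0.65 at 0.2 µM and -0.82 at 0.5 µM, and 78.0% of them were lower by more at 0.5 µM. The 1061 genes higher at both doses at 12 h had medians of 0.49 and 0.58 at 24 h, with 74.1% of them larger at 0.5 µM.

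Within (+)-JQ1, the higher dose lowered the oligodendrocyte genes further. Of the 21 genes of the lineage, 12 were lower at 0.5 than at 0.2 µM at 12 h and 16 at 24 h, with 0 higher (17 and 20 lower when adjusted over the list alone; camera adjusted p = 1.64e-35 and 2.27e-28, adjusted p = 4.06e-05 and 0.000163 with an estimated correlation). Gpr17 changed by log2 -2.83 ± 0.21 at 12 h and -2.58 ± 0.21 at 24 h. Gm98, the older symbol of the myelin regulatory factor Myrf, changed by -1.24 ± 0.20 and -1.68 ± 0.20, Bcas1, a gene of early myelinating cells, by -1.18 ± 0.21 at 12 h, and Mbp, which codes for myelin basic protein, by -1.63 ± 0.30 at 24 h (SE, n = 3 per group). The call of Bcas1 ended without (+) replicate 1 at 0.2 µM (adjusted p = 0.0592), and those of Bcas1 (0.0553) and Mbp (0.281) in the fit to the 6 libraries alone. Genes that rose with dose included Hist2h2aa1 (0.63 ± 0.12) and Efnb2, which codes for a ligand of Eph receptors (0.55 ± 0.11), at 12 h, and Pbx3, which codes for a homeodomain factor, at 24 h (0.63 ± 0.12). In the fit to the 6 libraries alone the calls of Hist2h2aa1 (adjusted p = 0.0513), Efnb2 (0.0602) and Pbx3 (0.18) ended. The call of Hist2h2aa1 also ended without replicate 1 or 2 at 0.2 µM (adjusted p = 0.1 and 0.056) or at 0.5 µM (0.0756 and 0.0753). That of Efnb2 ended without replicate 1 or 3 at 0.2 µM (0.126 and 0.0593) or replicate 2 or 3 at 0.5 µM (0.0791 and 0.12). With limma 89 genes differed at 12 h, 5 higher and 84 lower, and 297 at 24 h, 14 higher and 283 lower. The fit to the 6 libraries alone called 30 genes at 12 h, 2 higher and 28 lower, and 38 at 24 h, 0 and 38. A block on the numbers 1 to 3 within each time gave 237 genes at 12 h, 26 higher and 211 lower, and 598 at 24 h, 67 and 531. The split was 18 and 100 at 12 h and 33 and 197 at 24 h with the GC trend removed, and 43 and 259, and 92 and 490, with library weights. At 12 h it was 6 and 131 with a pseudocount of 0.1, and 14 and 118 without the 2 libraries with high Mir5105, which gave 4 and 202 at 24 h. Scaling by the median of ratios gave 26 and 202 at 24 h. At 12 h the count fell to 35 to 59 when any 1 of the 6 libraries was left out; at 24 h it was 137 or 167 without replicate 1 or 2 at 0.5 µM and 158 without replicate 2 at 0.2 µM. Without replicate 3 at 0.5 µM, 65 genes were higher and 310 lower at 24 h. At 24 h the fold changes correlated with GC content across genes (Spearman rho -0.459; -0.104 at 12 h).

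Within (−)-JQ1, the doses were hard to tell apart. At 12 h limma called 0 genes, with 59 at an unadjusted p under 0.05, and for 97.3% of the genes the 95% interval of the difference lay within 1 on the log2 scale. Gpr17 differed by log2 -0.03 ± 0.21, Hexim1 by -0.01 ± 0.09 and Myc by -0.05 ± 0.14 (SE, n = 3 per group). At 24 h 1 gene was lower at 0.5 µM, the small nucleolar RNA gene Snora65 (log2 -2.14 ± 0.27, adjusted p = 0.00182), named after its values were seen. At an unadjusted p under 0.05 there were 1673 genes, and 94.0% of the intervals lay within 1. Without (−) replicate 2 at 0.2 µM and 24 h, 1475 genes were called. The fold changes at 24 h correlated with GC content across genes (rho -0.472).

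Between the 12 h and 24 h libraries of (−)-JQ1, 2157 genes passed, 1520 higher and 637 lower at 24 h. The labels give no batch, so time in culture cannot be told apart here from a technical difference between these libraries. Eln, which codes for elastin (log2 2.27 ± 0.16), and Tagln, an actin-binding protein of smooth muscle (2.27 ± 0.19), rose. Egfr, the epidermal growth factor receptor (-1.43 ± 0.12), Etv5, a transcription factor downstream of fibroblast growth factor (-1.44 ± 0.25), and Actc1, a muscle actin (-1.84 ± 0.17), fell (SE, n = 6 per time). Of the 21 S phase genes, 16 were higher and 0 lower (17 and 0 when adjusted over the list alone; adjusted p = 1.27e-10, adjusted p = 0.314 with an estimated correlation). Of the 21 oligodendrocyte genes 11 were higher and 2 lower (11 and 4 when adjusted over the list alone; adjusted p = 0.0126, adjusted p = 0.389 with an estimated correlation). Mbp rose by log2 1.55 ± 0.21. Of the 16 Notch genes 7 were lower and 0 higher, also when adjusted over the list alone (adjusted p = 8.9e-06, adjusted p = 0.314 with an estimated correlation). The split was 1232 higher and 1014 lower after median-of-ratios scaling, 1390 and 1216 with the GC trend removed, 1986 and 1390 without the 2 libraries with high Mir5105, and 1082 and 376 in the fit to the 12 libraries alone. Without (−) replicate 1 at 0.2 µM and 24 h it was 1714 and 1124, and without (−) replicate 2 at 0.5 µM and 24 h 1125 and 423.

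The effect of (+) over (−)-JQ1 differed between doses in 6 genes at 12 h, 0 higher and 6 lower at 0.5 µM, and in 40 at 24 h, 1 and 39. Leaving out any 1 of the 12 libraries gave 1 to 5 and 21 to 62 genes. The fit to the 12 libraries alone gave 14 and 3, and library weights 33 and 17. With the numbers 1 to 3 as a block within each time the counts were 32 and 97. At 12 h there were 2 after median-of-ratios scaling, 3 with no filter on low values or with the GC trend removed, 10 with a pseudocount of 0.1 and 17 without the 2 libraries with high Mir5105. The oligodendrocyte list was lower in this difference at both times (2 and 7 of 21 members lower, 12 and 18 when adjusted over the list alone; adjusted p = 1.16e-31 and 5.76e-37, adjusted p = 8.34e-05 and 3.14e-05 with an estimated correlation). Gpr17 differed by log2 -2.80 ± 0.30 and -2.65 ± 0.30 (SE) and Tnr by -2.12 ± 0.29 at 24 h, a call that ended for Tnr in the fit to the 12 libraries alone (adjusted p = 0.0643). Between the times it differed in 3 genes at 0.2 µM, 1 and 2, and in 45 at 0.5 µM, 10 and 35, with 1 to 4 and 21 to 39 when any 1 of the 12 libraries was left out. At 0.2 µM limma called 0 genes in the fit to the 12 libraries alone, with a pseudocount of 0.1 or with library weights, and 1 after median-of-ratios scaling or without the 2 libraries with high Mir5105. At 0.5 µM there were 71 with the GC trend removed and 172 with library weights. With the numbers 1 to 3 as a block within each time there were 76 at 0.2 µM and 215 at 0.5 µM. Pcp4, which codes for a calmodulin-binding peptide of neurons, went from log2 -1.46 ± 0.22 at 12 h to 0.95 ± 0.22 at 24 h at 0.5 µM, a difference of 2.41 ± 0.32 (adjusted p = 0.000541). The mitosis list was lower in the difference between the times at both doses (0 and 1 of 22 members lower, 13 and 18 when adjusted over the list alone; adjusted p = 1.35e-21 and 4.1e-24, adjusted p = 0.232 and 0.13 with an estimated correlation). So was the cholesterol list (0 of 18 members at each dose, 1 and 11 when adjusted over the list alone; adjusted p = 1.19e-08 and 8.01e-15, adjusted p = 0.362 and 0.13 with an estimated correlation). For the other genes the main test did not show a difference. The 95% interval of the difference lay within 1 on the log2 scale for 91.9% and 89.3% of the genes between doses at 12 and 24 h and for 89.0% and 88.1% between times at 0.2 and 0.5 µM.

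**Figure D4:**
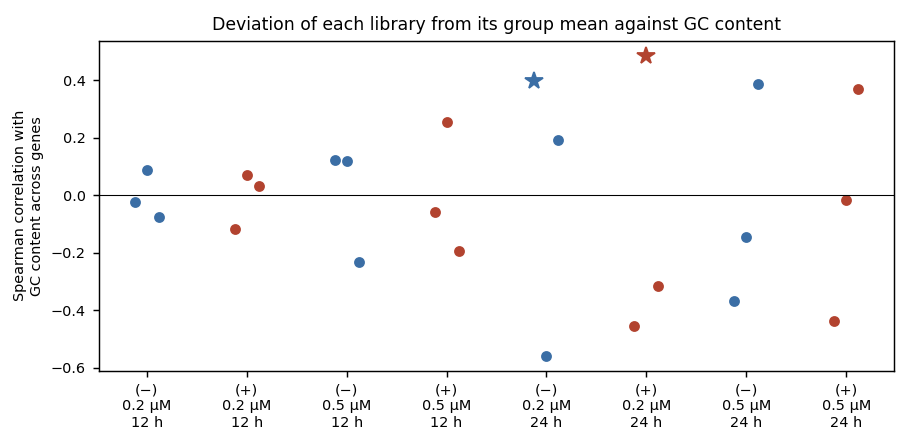
Spearman correlation across genes between GC content and the deviation of each library from its group mean (log2 FPKM), for (−)-JQ1 (blue) and (+)-JQ1 (red); stars mark the 2 libraries with high Mir5105. The 12 h libraries lie between -0.231 and 0.254, and the 24 h libraries between -0.558 and 0.486.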

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

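The tests of the 2 libraries that stand apart, of the histone genes at 12 h and over H4 copies, and of the neuronal genes were chosen only after the result was seen; the test of S phase over all 4 comparisons and the counts over other splits of the samples were not.

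The effect of (+) over (−)-JQ1 differed between the doses in 6 genes at 12 h and in 40 at 24 h, and each difference was tested as an interaction. A block on the numbers 1 to 3 within each time gave 32 and 97. Gpr17, the receptor of immature oligodendrocytes, went from log2 -3.37 at 0.2 µM to -6.17 at 0.5 µM at 12 h, a difference of -2.80 ± 0.30 (SE, adjusted p = 0.000103), and from -2.73 to -5.38 at 24 h, a difference of -2.65 ± 0.30. Enpp6 differed by -1.12 ± 0.19 at 12 h and by -1.91 ± 0.19 at 24 h. Its call at 12 h ended when any 1 of 9 of the 12 libraries was left out (adjusted p 0.0564 to 0.112), that is, each except (−) replicate 1 and (+) replicate 2 at 0.2 µM and (−) replicate 3 at 0.5 µM. It also ended with no filter (0.0534), in the groups alone (0.0555), after median-of-ratios scaling (0.11) and with the GC trend removed (0.0771). The uncharacterised gene 3110035E14Rik differed by -1.22 ± 0.21 at 12 h, a call that ended without any 1 library except (−) replicate 1 and (+) replicate 2 at 0.2 µM (adjusted p 0.0558 to 0.118), with no filter (0.0642) and after median-of-ratios scaling (0.115). The uncharacterised gene 1810041L15Rik differed by -0.98 ± 0.15 at 12 h. Its call ended without (+) replicate 1 or (−) replicate 2 or 3 at 0.2 µM, without (−) replicate 1 or 2 or (+) replicate 3 at 0.5 µM (adjusted p 0.0503 to 0.0945), and with the GC trend removed (0.0698). At 24 h Tnr differed by -2.12 ± 0.29 and Gm98 by -1.58 ± 0.28, calls that ended in the groups alone (0.0643 and 0.134) and for Gm98 with library weights (0.0845).

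Between 12 and 24 h the effect differed in 3 genes at 0.2 µM and in 45 at 0.5 µM, and in 76 and 215 with that block. Pcp4 was lower at 12 h and higher at 24 h at each dose, with a difference of 1.91 ± 0.32 at 0.2 µM and 2.41 ± 0.32 at 0.5 µM (SE). At 0.2 µM the call of Pcp4 ended without any 1 of 8 of the 12 libraries (adjusted p 0.0503 to 0.149), that is, each except (+) replicate 2 and (−) replicate 3 at 24 h and replicate 3 of both enantiomers at 12 h. It also ended with no filter (0.0503), in the groups alone (0.235), with a pseudocount of 0.1 (0.105), after median-of-ratios scaling (0.064) and with library weights (0.0632). At 0.5 µM, Bmper, which codes for a modulator of BMP signalling, differed by 1.45 ± 0.20, the vesicle protein gene Nsg2 by 1.03 ± 0.13, from log2 -1.90 to -0.87, and Jag1 by 0.99 ± 0.18. The call of Jag1 ended without (+) replicate 2 at 24 h or (−) replicate 2, (+) replicate 3 or (−) replicate 3 at 12 h (adjusted p 0.0503 to 0.0573) and in the groups alone (0.0574). Scrg1 differed by -1.63 ± 0.27, Acta2 by -1.57 ± 0.21, Enpp6 by -1.49 ± 0.19, and the uncharacterised gene 9630013A20Rik by -1.22 ± 0.20. In (+)-JQ1 at 0.5 µM, Enpp6 lay below 1 FPKM at both times, while its level in (−)-JQ1 rose with time. Its difference thus follows the level in (−)-JQ1, and a further fall in (+)-JQ1 could hardly be measured.

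For these 4 counts the splits decide nothing about chance. A split that exchanges doses or times within 1 enantiomer carries the effect of the dose or the time itself, which is no part of the difference tested. Of 100 drawn splits of the same libraries each, the real one included, as many genes came from 12 for the dose difference at 12 h (real 6, highest other 14), 11 at 24 h (real 40, highest other 879), 16 for the time difference at 0.2 µM (real 3, highest other 827) and 8 at 0.5 µM (real 45, highest other 2087). The split with 2087 genes exchanged all libraries of (+)-JQ1 between the times, so it carries the effect of time. The split with 827 exchanged replicates 1 and 2 of (+)-JQ1 between the times, among others, and carries part of that effect. The split with 879 exchanged replicates 1 and 3 of (−)-JQ1 between the doses at 24 h and points to a structure of the samples. The 4 comparisons of the enantiomers have 10 splits each, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes, with real counts of 3846, 5281, 4529 and 5273 and highest others of 1, 1, 2328 and 1. The split with 2328 genes put the first (−) library and the second (+) library at 0.2 µM and 24 h together, a structure of the samples taken up next. The dose comparisons also have 10 splits each, too few for a share under 0.05. Within (+)-JQ1, 1 split gave as many genes at each time (real 89 and 297, highest other 1 and 1). Within (−)-JQ1, 10 splits did at 12 h (real 0, highest other 1) and 3 at 24 h (real 1, highest other 1839, again a structure of the samples). For (−)-JQ1 at 24 against 12 h, 1 of 100 splits gave as many genes (real 2157, highest other 821), a share under 0.05. That excludes a chance split of these libraries. It cannot tell the time in culture from a technical difference between the 12 h and the 24 h libraries.

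The first pattern weighed is that the first (−) library and the second (+) library at 0.2 µM and 24 h stood apart from the others of their groups, with Mir5105 at 42.7% and 46.9% of the FPKM sum. A swap between the enantiomers is excluded: Hexim1 was at 52.2 FPKM in the (+) library, where the other (+) libraries ran from 51.1 to 72.1, and at 19.3 in the (−) library, where the others ran from 16.8 to 21.8 (n = 11 each). A GC bias remains open, since the deviations from the group mean correlated with GC content across genes with rho 0.398 and 0.486, above the 12 h libraries (-0.231 to 0.254, n = 12). It may not be particular to this pair, because the other 24 h libraries ran from -0.558 to 0.387 (n = 10). The low end of that range came from (−) replicate 2, a group-mate of the first (−) library, whose deviation is taken from the same group mean. Library weights, lower for libraries that deviate more, were 0.290 for this group-mate and 0.265 and 0.251 for the pair. It therefore deviated about as much, and it stayed in when the pair was left out. The libraries at 0.5 µM and 24 h share no group with the pair and ran from -0.436 to 0.387. The labels give no batch and no biological difference for these libraries, so no biological explanation was tested.

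The second pattern weighed is the rise of histone genes in (+)-JQ1. More cells in S phase would be expected to raise the S phase list, which at 24 h and 0.2 µM had a median of log2 -0.67. That argues against this cause at 24 h and does not exclude it. The share of cells in S phase was not measured, and (+)-JQ1 could lower these RNAs without changing that share. The call of the list at 24 h also ended with an estimated correlation. At 12 h the median of the histone list exceeded that of the S phase list by at least 1.66, against an SD of 0.42 and 0.43 among the S phase genes. For the H4 genes, reads that only moved between near-identical copies are excluded. The summed FPKM of 13 H4 genes was 3.55 to 13.6 times as high in (+) as in (−)-JQ1 over 12 same-numbered pairs. The other histone families were not summed, so this was not tested for them. A direct effect on the histone genes may explain the rise. So may histone RNA that gained poly(A) tails and so entered poly(A)-selected libraries. The data at hand did not test either.

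The third pattern weighed is that neuronal genes went both ways, with Tubb3 and Syt1 higher and Dcx and Gap43 lower. A higher share of neurons among the cells stays open: at least 7 members of the neuronal cytoskeleton and synapse list were lower in each comparison, but that count restates the pattern and decides nothing about the share. GC bias is excluded as the whole cause, since 94.4% of the list's 54 calls (51) stayed with the GC trend removed. An effect of (+)-JQ1 on separate neuronal genes may account for it and was not tested.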

How the results depend on the processing

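Among the tests below, those with a pseudocount of 0.1, median-of-ratios scaling, the GC trend removed, library weights, no variance trend, short RNA genes left out or the 2 libraries with high Mir5105 left out were chosen after seeing the data; the others were planned. Across 278 values of named genes, 246 of them called, and 4868 alternative values, no called value changed direction. Genes named for the largest called changes in these data could hardly reverse. In the main comparisons they also had to change the same way in all 3 same-numbered pairs. The lack of reversals is therefore little evidence of stability. With 1 library left out, called values kept their call in 1528 cases and lost it in 98, and in fits to the groups compared alone 21 of 246 lost it. The 4 total counts for the enantiomers stayed within 1.5 times except at 0.2 µM and 24 h. There the fit to its 6 libraries gave 2056, 2038 of them among the 4529 genes. The balance of directions did not hold. Of the genes called, 29.5% to 35.9% were higher in the main fit. That share was 42.9% to 49.1% after median-of-ratios scaling and 47.5% to 52.0% with the GC trend removed. The other counts below moved, in the order named, and the cause was not tested. No filter on low values: 3 for the dose difference at 12 h, 1 and 7 for the (−) dose at 12 and 24 h. A replicate block within each time: dose difference 32 and 97, time difference 76 and 215, (+) dose 237 and 598. The groups compared alone, with fewer samples: dose difference 14 and 3, time difference at 0.2 µM 0 by limma, (+) dose 30 and 38, (−) dose at 12 h 2. Pseudocount of 0.1: dose difference at 12 h 10, time difference at 0.2 µM 0, (+) dose at 12 h 137. Median-of-ratios scaling: 2 and 1 for the same differences. GC trend removed: dose difference at 12 h 3, time difference at 0.5 µM 71. Without the 2 libraries: dose difference at 12 h 17, time difference at 0.2 µM 1, (−) dose at 24 h 3, (−) time 3376. Library weights: dose difference 33 and 17, time difference 0 and 172, (+) dose 302 and 582. Short RNA genes left out: (−) dose at 24 h 0, since its gene is Snora65.

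Leaving out 1 library at a time gave 3018 to 3235, 4452 to 4616, 3656 to 4973 and 4509 to 4805 genes for the enantiomers, 1 to 5 and 21 to 62 for the dose differences, 1 to 4 and 21 to 39 for the time differences, 35 to 59 and 137 to 375 for the (+) dose, 0 to 0 and 1 to 1475 for the (−) dose, and 1511 to 2838 for (−) time. With the numbers 1 to 3 as a block the counts were 3960, 5438, 4660 and 5399 for the enantiomers. Same-numbered enantiomer pairs correlated by -0.345 to 0.358 (median 0.108) in their deviations across genes, which are not independent replicates, and 17 of the 24 libraries correlated best with their own number, a hint from the data and not the design. Of the 10, 11, 8 and 11 lists called for the enantiomers, 2 were called in each with an estimated correlation; fry called 17, 17, 16 and 19, without the mitosis list at 0.5 µM and 12 h (adjusted p = 0.301). With the replicate block the interferon list at 0.2 µM and 12 h was not called (adjusted p = 0.0522).

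Some values of genes that were not called changed sign (log2). Leaving out 1 library gave at 0.2 µM and 12 h -0.106 to 0.00303 for Brd3, -0.0275 to 0.319 for Hes1, -0.189 to 0.0595 for Olig1 and -0.137 to 0.201 for Slc1a3. It gave -0.153 to 0.180 for Slc1a3 at 0.5 µM and 12 h, and at 0.2 µM and 24 h -0.288 to 0.0114 for Neurod1, -0.445 to 0.225 for Olig1 and -0.00369 to 0.233 for Sox2. Scaling gave 0.0208 for Brd3 and 0.0281 for Olig1 at 0.2 µM and 12 h and 0.0313 for Olig1 at 24 h. Removing the GC trend gave 0.0492 for Brd3, 0.101 for Olig1 and 0.0585 for Olig2 at 12 h and 0.0625 for Olig1 at 24 h, and weights gave -0.00298 for Slc1a3 at 0.5 µM and 12 h. Other count normalizations and a second test on counts were planned and not run, because the files hold FPKM. The absolute depth is unknown, so its limit on low genes could not be computed.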

Other observations

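Of the tests of genes that rise with time, those without the 2 libraries with high Mir5105, with the GC trend removed and on genes lower with time were chosen only after the result was seen. The genes in the next paragraph were chosen after their values were seen. Changes are given in the order 0.2 µM 12 h, 0.5 µM 12 h, 0.2 µM 24 h and 0.5 µM 24 h as log2 ± SE (n = 3 per group).

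Bcl2l11, which codes for the cell death protein Bim, was higher in (+)-JQ1 by 0.64 ± 0.16, 1.05 ± 0.16, 0.82 ± 0.16 and 1.09 ± 0.16, and the death receptor gene Fas changed by -0.83 ± 0.22, -0.85 ± 0.22, -1.23 ± 0.22 and -1.26 ± 0.22. Among CDK inhibitors, Cdkn1b rose by 0.43 ± 0.09, 0.44 ± 0.09, 0.25 ± 0.09 and 0.48 ± 0.09, while Cdkn1c changed by -0.74 ± 0.25, -0.92 ± 0.25, -1.36 ± 0.25 and -1.80 ± 0.25. The activator of S phase genes E2f3 changed by -0.85 ± 0.12, -1.13 ± 0.12, -0.93 ± 0.12 and -1.32 ± 0.12. Of the interneuron list, Calb2, which codes for the calcium-binding protein calretinin, changed by -0.95 ± 0.22, -0.89 ± 0.22, -1.84 ± 0.22 and -2.17 ± 0.22. Camk2b, a kinase of synapses, changed by -1.16 ± 0.12, -1.42 ± 0.12, -1.15 ± 0.12 and -1.31 ± 0.12, and Sox11, a factor of young neurons, by 1.04 ± 0.25, 1.25 ± 0.25, 0.82 ± 0.25 and 0.97 ± 0.25. Egfr was higher in (+)-JQ1 at 24 h, by 0.63 ± 0.17 (adjusted p = 0.00577) and 0.51 ± 0.17 (adjusted p = 0.019), and was not called at 12 h (-0.10 ± 0.17 and -0.17 ± 0.17). Its effect was not shown to differ between the times (0.73 ± 0.24, adjusted p = 0.675, and 0.68 ± 0.24, adjusted p = 0.386).

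It was tested whether (+)-JQ1 lowers the genes that rise with time in (−)-JQ1. Of 646 genes higher at 24 than at 12 h in (−)-JQ1 at 0.2 µM, 307 (47.5%) were lower in (+)-JQ1 at 0.5 µM and 12 h. Of all genes tested, 26.1% were (odds ratio 2.71, Fisher's exact test, two-sided p = 5.28e-33). Genes are not independent replicates. These comparisons share no library, but both calls used the same estimate of each gene's spread from all 24 libraries. A gene with a small spread is called more easily in both, so the calls are not independent. The share lower in (+)-JQ1 was 40.3% of 725 genes without the 2 libraries with high Mir5105, and 38.6% of 648, against 22.4%, with the GC trend removed. Of 193 genes lower with time, 40.4% were lower in (+)-JQ1 as well (odds ratio 1.94, Fisher's exact test, two-sided p = 1.46e-05). Genes higher in (+)-JQ1 were 13.3% of those that rise with time and 12.95% of those that fall, against 12.2% of all (Fisher's exact test, two-sided p = 0.356 and 0.739). The genes that change with time in either direction were thus enriched among those lower in (+)-JQ1, and were not shown to be among those higher. The cause was not tested.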
